A study of Arabidopsis thaliana with 12 samples.

How the data were processed

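Gene expression was measured by RNA-seq in 12 libraries made from detached leaves of Arabidopsis thaliana Col-0, the usual laboratory accession of this plant. There were 4 treatment groups with 3 libraries each: mock, diacetyl vapour, ABA, and ABA with diacetyl vapour. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted with a plant column kit and standard Illumina libraries were made; whether the libraries kept the strand is not given in the sources used here.

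The deposited files held 1 whole-number count per gene and library, not normalized, for 33610 loci. The submitters' processing notes name cutadapt 1.4 (adapter trimming), TopHat (alignment), HTSeq (read counting), edgeR and the TAIR10 genome build. Their settings, and the versions of the other tools, are not given in the sources used here. The counts were used as the authors deposited them, and no file held a column of another sample. Gene names came from a RefSeq table of the TAIR10.1 assembly, matched by locus identifier; 28932 loci had a row in it. Coordinates were not printed because the build of that table differs in name from that of the counts. Another 3884 loci carried a version suffix after the locus number, and these took 0.126% to 0.183% of the counts of a library.

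Total counts ran from 8627735 to 16967559 in 11 libraries and were 2306127 in ABA with diacetyl replicate 3. A single count was worth 0.434 CPM (counts scaled to a fixed library total) in that library and 0.0589 to 0.116 CPM in the others. The floor of 3 counts was 1.30 CPM there and 0.177 to 0.348 CPM elsewhere. Intervals and floors cover counting error only. No 2 libraries of a group agreed within sampling noise in a chi-square test of counts over genes summing to at least 20 counts: chi-square per degree of freedom was 6.86 to 103.

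Genes were filtered with filterByExpr by group, which left 18452 genes. TMM factors scaled the library sizes. All 12 libraries were fitted in 1 model with a mean per group, using edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.069, a biological coefficient of variation of 0.263. The 6 contrasts were ABA against mock, diacetyl against mock, ABA with diacetyl against ABA, ABA with diacetyl against diacetyl, ABA with diacetyl against mock, and the interaction. The interaction is the log2 fold change of ABA in the presence of diacetyl minus that of ABA alone. Unless said otherwise, every adjusted p of a gene in the text is from this edgeR test. For genes with 1 to 3 counts over a group, the ratio of counts is given with an exact 95% interval, and for genes with no count in a group a lower bound against a floor of 3 counts over the group.

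The groups compared, the tests, 27 gene lists and the rule for named genes were fixed before the data were examined. The lists held 449 members, of which 442 matched a locus by symbol or synonym and 403 were tested. Each list was tested with camera (limma 3.58.1) on voom log-CPM values with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. An estimated correlation and fry were alternatives. Member calls were counted over all genes tested and adjusted over the list alone. A list score was the mean of log2(CPM + 1) over its members in a library. Guard cell, vascular, epidermis, root and dividing cell markers were among the lists, as signs of a different mix of cells. Genes named in the text were up to 12 higher and 12 lower with the largest fold in a contrast among calls with groups that did not overlap and a mean of at least 1 CPM, up to 4 members of each list with the smallest p, and 11 fixed genes (RD29A, RD29B, RAB18, NCED3, ABI1, HAI1, ORE1, NAP, SEN1, NYE1 and PYL5) in every contrast. For the interaction, the rule did not ask for separate groups.

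Process terms from the notes of the reference annotation were tested for enrichment with a one-sided Fisher's exact test, higher and lower calls apart. There were 249 terms of 10 to 500 genes, over the 8516 tested genes with a term. This test was added after the data had been seen. Correlations and slopes of fold changes were set beside 50 simulations. Those of unchanged groups drew all 12 libraries from the mock means, and both folds shared the same drawn mock libraries. Those without an interaction kept the fitted effects of ABA and diacetyl. In both, each gene was drawn independently.

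The tests were tried on simulated counts over 18452 genes with 200 changed genes. For ABA against mock, edgeR recovered 4.48% of genes changed 1.5-fold, 26.2% of those changed 2-fold and 76.4% of those changed 4-fold, and 5.13% of its calls were false. For the interaction it recovered 0%, 2.99% and 51.5%, with 0% false calls; DESeq2 had 32.2% false calls there and 19.0% for ABA against mock. The slope came out as 0.87 where the simulated effect was equal in both settings and as 0.42 where it was reduced by a factor of 0.5. In the list test, a 2-fold change put into the unfolded protein response list gave a camera adjusted p of 1.77e-17, with 0 other lists called. The 200 changed genes were fewer than the calls of any contrast in the data, so the shares recovered may differ there. Genes were drawn independently, so the list test does not show how camera behaves with correlated genes.

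Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, fold thresholds, fits with only the groups compared, a fit with the replicate number as a block, and leaving out each library. Leaving out both libraries that stood apart (diacetyl replicate 2 and ABA with diacetyl replicate 3) was added after the data had been seen. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 made the term tests and plots. Members of close gene families, such as ribosomal proteins, histones, light-harvesting proteins and ABA receptors, can share reads, so the value of a single member is uncertain. Without a stated strand, a gene cannot be told from an antisense partner.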

Results

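The data came from the fourth rosette leaf of 30-day-old plants, detached and kept in the dark in a divided dish for 30 min. ABA (abscisic acid, the hormone of drought and stress responses) was given as 3 mL of a 100 µM solution under the leaves. Diacetyl, a volatile diketone that bacteria release, reached the leaves as vapour from 300 µL of a 10 mM solution on the other side of the dish. Mock dishes held 300 µL of water on that side, and no label says what that side held in the ABA dishes. Every comparison with the ABA dishes, ABA against mock included, may therefore carry a difference on that side too. The series asks whether a microbial compound relieves the leaf senescence that ABA brings on. There were 3 libraries per group, with 8627735 to 16967559 counts in 11 of them and 2306127 in ABA with diacetyl replicate 3. No label says that the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

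Correlations of log-CPM between libraries of a group were 0.915 to 0.980. The first principal component held 39.6% of the variance and put the ABA-treated libraries at 44.1 to 74.3 and the others at -90.5 to -1.87. The second held 21.4% and put diacetyl alone at -96.3 to -38.5, ABA with diacetyl at -24.2 to -12.7, and mock and ABA alone at 32.2 to 46.1. Diacetyl replicate 2 lay farthest out, at -96.3. Diacetyl replicate 1 had a plastid-encoded share of 0.113% of its counts, against at most 0.0323% in the other libraries, and an rRNA share of 0.178% against at most 0.0503%.

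**Figure D1:**
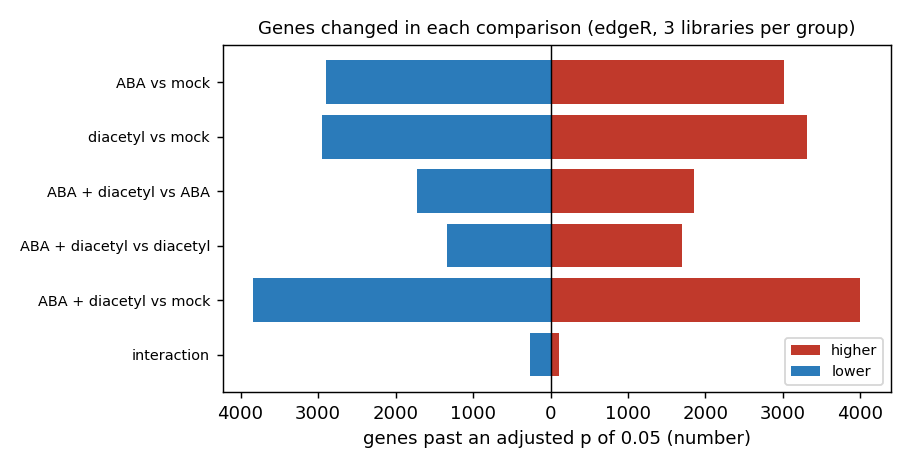
Number of genes higher (right) and lower (left) in each comparison, edgeR adjusted p under 0.05, 3 libraries per group. ABA with diacetyl against mock had the most calls, 3996 higher and 3838 lower, and the interaction had 104 and 260.

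ABA alone raised the known ABA response genes within 30 min. Of 32 tested ABA-responsive genes, 29 rose against mock (30 adjusted over the list alone). RAB18, a dehydrin, rose from 15.2 ± 4.41 to 229 ± 35.6 CPM (SD, n = 3), a 15.1-fold change. RD29A rose 3.38-fold to 4361 ± 474 CPM and RD29B 86.1-fold, both being stress genes with ABA response elements. The late embryogenesis abundant gene LEA7 had 719 times the mock level (95% exact interval 245 to 3490), and AFP1, which encodes a partner of the transcription factor ABI5, rose 105-fold. The log2 fold of LEA7 was 9.30, and 10.01 without mock replicate 3.

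The ABA signalling pathway itself moved in opposite directions. All 8 tested clade A PP2C phosphatases, which hold the pathway off in the absence of ABA, rose: HAI1 from 0.908 ± 0.979 to 523 ± 138 CPM, ABI1 9.99-fold and HAB1 22.9-fold. Of 9 tested PYR/PYL receptors, 7 fell, among them PYR1 (7.61-fold lower), PYL5 (9.87-fold lower) and PYL6 (38.6-fold lower). Of 10 SnRK2 kinases and ABF/ABI factors, 6 rose and 2 fell (6 and 3 adjusted over the list alone), with ABF3 75.0-fold higher. Of 11 genes of ABA synthesis and catabolism, 8 rose (9 adjusted over the list alone), including NCED3, the rate-limiting step of synthesis (9.55-fold), and CYP707A3, an ABA hydroxylase (3.81-fold). The log2 fold of HAI1 was 9.09, and 10.46 without mock replicate 3; that of PYL6 was -5.27, and -6.86 without ABA replicate 2.

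Senescence genes rose in part. In the leaf senescence list 9 of 20 rose, also adjusted over the list alone; the senescence regulators NAP and ORE1 rose 10.6-fold (42.0 ± 50.2 to 448 ± 106 CPM) and 4.89-fold. SEN1 was at 1.25 ± 1.18 CPM in mock and 6.10 ± 5.88 CPM with ABA, which did not pass the edgeR test (adjusted p = 0.199). Of 7 genes of chlorophyll breakdown, 6 rose, including NYE1, the magnesium dechelatase (4.40-fold), and PAO, pheophorbide a oxygenase (log2 fold 1.85). ORE1 lost its call without mock replicate 2 (edgeR adjusted p = 0.0602), and without mock replicate 3 the log2 folds of NAP and ORE1 were 5.04 and 3.14, against 3.41 and 2.29 with all libraries.

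Jasmonate genes rose in 10 of 25 cases and fell in 1, with VSP2 15.9-fold higher. In the detoxification list 17 of 32 rose and 1 fell (18 and 1 adjusted over the list alone), led by the aldehyde dehydrogenase ALDH7B4 with a log2 fold of 4.33. The unfolded protein response list had 7 of 12 higher (9 adjusted over the list alone), with its regulator BZIP60 2.66-fold higher. Reactive oxygen enzymes rose in 5 of 15 cases. Epidermis markers rose in 4 of 5, including the wax gene CER6 (2.82-fold) and the lipid transfer protein gene LTP1 (5.66-fold). CER1, another wax gene, rose 361-fold, MYB102 rose 310-fold and LBD1 was at 600 times the mock level (95% exact interval 205 to 2910). The guard cell factor MYB60 fell 9.41-fold, the sugar starvation gene DIN10 fell 16.6-fold, and WRKY70, a salicylate response factor, fell 5.54-fold. WRKY70 lost its call without ABA replicate 1 (edgeR adjusted p = 0.0953). GASA6 was lower by an amount that depended on single libraries: its log2 fold was -7.00, but -4.84 without mock replicate 1, -6.39 without ABA replicate 2 and -11.52 without ABA replicate 3, and limma-voom did not call it (adjusted p = 0.185). Without mock replicate 3 the log2 fold of LBD1 was 11.92 (9.06 with all libraries), and without ABA replicate 2 that of MYB60 was -4.08 (-3.23).

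The other lists had calls in both directions or few calls. Photosynthesis had 9 higher and 7 lower of 35, with LHCA4 8.29-fold higher. Dark and sugar starvation had 5 and 5 of 19, early immune and wound response 7 and 5 of 27, the circadian clock 7 and 3 of 20, ethylene 6 and 3 of 19, and auxin 3 and 3 of 15. Chlorophyll synthesis had 2 higher and 4 lower of 11, cytokinin 2 and 3 of 10, heat shock 3 and 3 of 17, and guard cell markers 1 and 2 of 8. Salicylate genes fell in 3 of 18 cases and vascular markers in 1 of 9, and glyoxalase genes rose in 1 of 4. Adjusted over the list alone, photosynthesis had 9 and 8, cytokinin 2 and 5, and guard cell markers 1 and 4. Of 2 root and 3 dividing cell markers edgeR, DESeq2 and limma-voom called 0, with 0 at an unadjusted p under 0.05 by edgeR. The median and the mean log2 fold differed in sign for photosynthesis (-0.01 and 0.27) and auxin (-0.15 and 0.44). The 8 process terms enriched among higher genes included response to salt stress (73 of 225, 38.9 expected, Fisher's exact adjusted p = 3.77e-06) and to water deprivation (28 of 69, 11.9 expected, adjusted p = 0.000499). Among lower genes they included translation (92 of 361, 59.6 expected, Fisher's exact adjusted p = 0.000371), ribosome biogenesis (31 of 99, 16.3 expected, adjusted p = 0.0062) and rRNA processing (12 of 25, 4.13 expected, adjusted p = 0.0062). The mean log2(CPM + 1) of translation genes was 5.68 to 5.87 in the ABA libraries and 5.96 to 6.17 in mock.

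In all, 5912 genes passed the edgeR test for ABA against mock, 3009 higher and 2903 lower. The groups of 9803 genes (53.1%) did not overlap, where chance gives 10%, among them 5817 of the 5912 called genes. This held for all 32 genes named above with a call, but the naming rule asked it of those picked by fold. The least certain of those calls had an edgeR adjusted p of 0.0251 (WRKY70, log2 fold -2.47 ± 0.74 SE) and the most certain 2.47e-07 (AFP1, 6.72 ± 0.28). The count of called genes was 3815 without ABA replicate 1. By camera 12 of 27 lists passed, and with an estimated correlation 0 did (4 at an unadjusted p under 0.05), while fry passed 13. The camera list adjusted p was 9.61e-21 for ABA-responsive genes (adjusted p = 0.0968 with an estimated correlation), 3.07e-09 for the phosphatases (adjusted p = 0.0968 with an estimated correlation) and 0.000135 for the receptors (adjusted p = 0.275 with an estimated correlation). It was 5.90e-05 for ABA synthesis and catabolism (adjusted p = 0.0968 with an estimated correlation), 0.000339 for chlorophyll breakdown (adjusted p = 0.151 with an estimated correlation) and 0.000713 for jasmonate (adjusted p = 0.595 with an estimated correlation). The SnRK2, senescence, reactive oxygen, detoxification, unfolded protein and epidermis lists also passed camera, each with an adjusted p = 0.471 with an estimated correlation. Other groupings of the same 6 libraries took up to 15 lists past the camera test. Each of them set unequal numbers of ABA libraries on its 2 sides, so part of the ABA effect stayed in its contrast. Their list counts therefore do not decide whether the lists passed by chance.

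**Figure D2:**
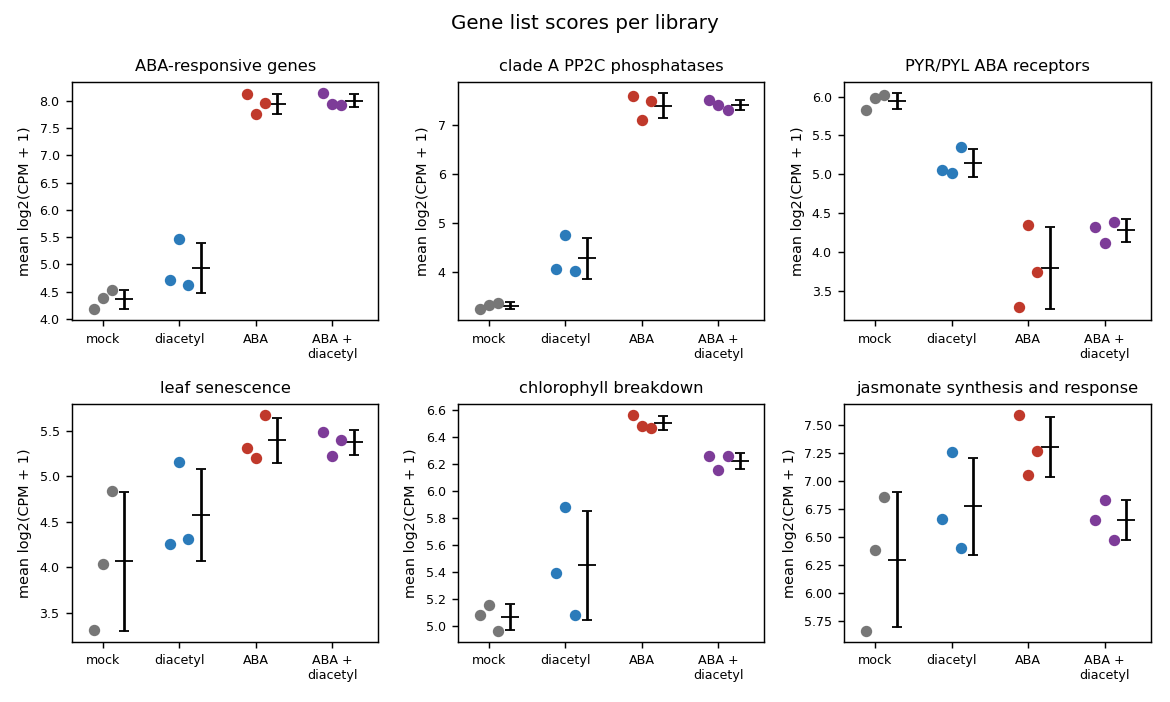
Mean log2(CPM + 1) over the members of 6 gene lists in each library (points), with the group mean and SD beside them (n = 3). ABA-responsive genes stood at 4.36 in mock, 4.94 with diacetyl, 7.95 with ABA and 8.003 with ABA and diacetyl.

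Diacetyl vapour alone lowered genes of the translation machinery. Members of the detoxification, clock and ABA lists rose, though 0 of 27 lists passed the main camera test. Over all 18452 genes tested, 3311 were called higher and 2950 lower, the share to set beside the list counts below. Of 361 genes with the process term translation, 208 fell against mock where 51.8 were expected (Fisher's exact adjusted p = 6.11e-84), and of 99 with the term ribosome biogenesis 60 fell where 14.2 were expected (adjusted p = 1.71e-24). The mean log2(CPM + 1) of translation genes was 6.09 ± 0.113 in mock and 5.53 ± 0.215 with diacetyl (SD, n = 3), and it was lowest in diacetyl replicate 2, at 5.29. Of 32 detoxification genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), with the cytochrome P450 CYP81D11 37.6-fold higher and the glucosyltransferase UGT75B1 15.2-fold higher. CYP81D11 was at 42.9, 318 and 12.8 CPM in diacetyl replicates 1, 2 and 3. Without replicate 2 the log2 folds of CYP81D11 and UGT75B1 were 3.11 and 3.199, against 5.23 and 3.92 with all libraries, and without replicate 3 that of CYP81D11 was 5.83.

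Parts of the ABA pathway moved with diacetyl alone. Of 32 ABA-responsive genes 11 rose, including the NAC factor ATAF1 (10.1-fold, to 213 ± 149 CPM; log2 fold 3.34, and 2.69 without diacetyl replicate 2), and 4 of 8 phosphatases rose, including HAB1 (2.99-fold) and PP2CA (3.64-fold). The kinase gene OST1 rose 2.87-fold among 4 of 10 in its list (5 adjusted over the list alone), and NCED3 rose 6.50-fold among 4 of 11 in ABA synthesis and catabolism. Of the receptors 3 of 9 fell, with PYR1 3.55-fold and PYL5 2.47-fold lower. RD29A (log2 fold -0.24 ± 0.19 SE, edgeR adjusted p = 0.356), RAB18 (0.03 ± 0.37, adjusted p = 0.967), RD29B (adjusted p = 0.242), ABI1 (adjusted p = 0.109) and HAI1 (adjusted p = 0.0888) did not pass. Nor did NAP (42.0 CPM in both groups, edgeR adjusted p = 0.999), ORE1 (adjusted p = 0.409) and NYE1 (adjusted p = 0.905). The log2 fold of NAP ran from -0.547 to 1.63 when single libraries were left out, so its equal means do not show equal levels.

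Transcripts of AOP2 and CYP79F1, which are assigned to the synthesis of aliphatic glucosinolates, sulphur-rich defence compounds, rose 47.3-fold and 26.9-fold. Whether either gene makes an active enzyme in these leaves was not measured. CYP79F1 went from 16.4 ± 10.7 to 442 ± 380 CPM. Of 20 clock genes 11 rose and 1 fell by edgeR (14 and 2 adjusted over the list alone), 5 and 1 by limma-voom, and 4 and 1 by edgeR without diacetyl replicate 2 and ABA with diacetyl replicate 3. The clock gene PRR7 had a log2 fold of 3.55, 1.66 without diacetyl replicate 2 and 4.13 without replicate 3. EIN2, a central ethylene signalling gene, rose 2.31-fold among 5 of 19 in its list. MYC2 rose 3.76-fold among 7 of 25 jasmonate genes, the alternative oxidase AOX1A (log2 fold 1.85) among 3 of 15 reactive oxygen enzymes, and LHCA4 4.55-fold among 8 of 35 photosynthesis genes (7 adjusted over the list alone). Of 18 salicylate genes 3 fell (1 adjusted over the list alone), including WRKY70 4.27-fold and NPR1, the salicylate receptor, 1.83-fold. SPCH, which starts the stomatal lineage, was lower, with a log2 fold of -3.90 (-5.78 without diacetyl replicate 1 and -3.21 without replicate 3). TPS04, a terpene synthase, had a log2 fold of -3.43, and -2.01 without mock replicate 3. GH3.5, an auxin-conjugating enzyme, rose 11.7-fold (log2 fold 3.55). Without diacetyl replicate 2 the log2 fold was 4.93 for AOP2, 4.03 for CYP79F1 and 2.94 for GH3.5. It was 6.16 for AOP2 and -3.04 for WRKY70 without replicate 3, and 5.36 for CYP79F1 without mock replicate 3. Limma-voom did not call AOP2 (adjusted p = 0.0759), PRR7 (adjusted p = 0.0828) or TPS04 (adjusted p = 0.0974).

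The remaining lists were called as follows. Senescence had 3 of 20 higher (2 adjusted over the list alone), chlorophyll breakdown 1 of 7, chlorophyll synthesis 3 of 11, dark and sugar starvation 7 of 19, and the unfolded protein response 3 of 12. DESeq2 called 6 of 11 chlorophyll synthesis genes higher, and 7 higher and 2 lower of 19 dark and sugar starvation genes. Early immune genes had 1 higher and 3 lower of 27, heat shock 3 and 1 of 17 (0 and 1 by limma-voom, 4 at an unadjusted p under 0.05), auxin 3 and 1 of 15, cytokinin 3 and 1 of 10, guard cell markers 1 and 1 of 8, vascular markers 2 of 9 higher, epidermis 2 of 5 and glyoxalase 1 of 4. The heat shock gene HSP17.4 (4.63-fold), SEN1 (14.9-fold) and the factor LBD39 (333 times the mock level, 95% exact interval 59.3 to 13200) rose largely in diacetyl replicate 2, where they stood at 190, 53.8 and 27.0 CPM against at most 29.1, 2.94 and 1.47 in the other diacetyl libraries. Without that library their log2 folds were 0.56, 0.88 and 5.45, against 2.21, 3.89 and 8.24 with all. That of SEN1 was 4.93 without mock replicate 3 and 4.50 without diacetyl replicate 3, and that of LBD39 was 9.96 without mock replicate 2. HSP17.4 and SEN1 lost their calls without diacetyl replicate 2 (edgeR adjusted p = 0.226 and 0.511) and with limma-voom (adjusted p = 0.13 and 0.25). Calls were also lost for WRKY70 without diacetyl replicate 1 (edgeR adjusted p = 0.121) and PYL5 without mock replicate 2 (adjusted p = 0.0733).

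In all, 6261 genes passed the edgeR test for diacetyl against mock, 3311 higher and 2950 lower, and 3217 did with only these groups in the fit. Of the 24 called genes named here limma-voom did not call 5. Upper-quartile scaling shifted the median fold by -0.115 (log2) and split the calls 2639 higher and 3692 lower, and the medians of the glyoxalase and auxin lists changed sign with it. The median of translation genes was -0.61 on the main scale, and 240 of them fell with that scaling. The groups of 7794 genes (42.2%) did not overlap, where chance gives 10%, among them 5850 of the 6261 called genes. This held for 22 of the 24 called genes named here, not for WRKY70 and SEN1, but the naming rule asked it of those picked by fold. The count of called genes was 4021 without mock replicate 2 and 5233 without both libraries that stood apart, and 174 translation genes then fell. By camera 0 of 27 lists passed (12 at an unadjusted p under 0.05, 0 with an estimated correlation, 2 by fry, 8 with the replicate number as a block).

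**Figure D3:**
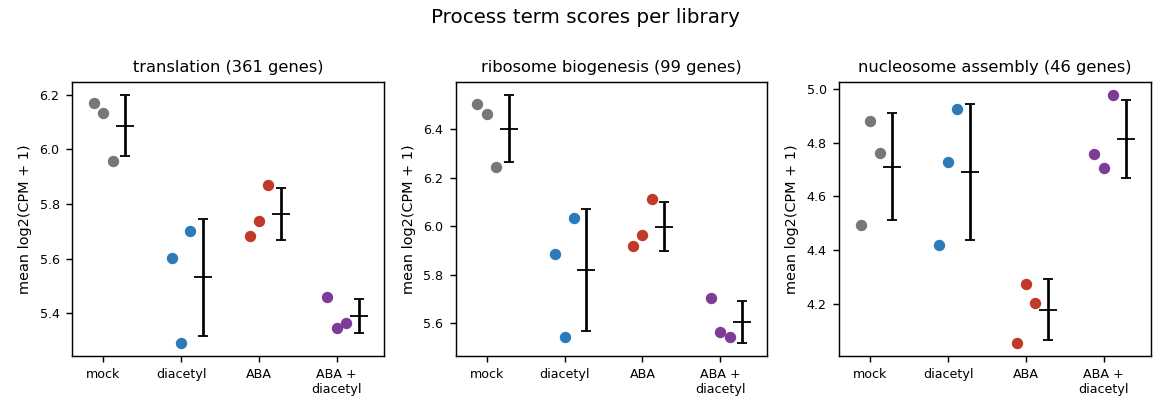
Mean log2(CPM + 1) over the genes of 3 process terms in each library (points), with the group mean and SD beside them (n = 3). Translation genes stood at 6.09 in mock, 5.53 with diacetyl, 5.76 with ABA and 5.39 with both.

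Adding diacetyl to ABA is the comparison the series asks about, and it moved neither the ABA response genes nor the senescence regulators NAP and ORE1 past the test. No label says what the vapour side of the ABA dishes held, so it is not known whether these groups differed in diacetyl alone. Of 32 ABA-responsive genes, edgeR called 0 (4 at an unadjusted p under 0.05; DESeq2 called 2 higher and limma-voom 1 lower). RD29A was at 4361 ± 474 CPM with ABA and 6242 ± 841 CPM with both (log2 fold 0.52 ± 0.19 SE, adjusted p = 0.083, edgeR), and RAB18 at 229 ± 35.6 and 257 ± 85.3 CPM. The senescence genes NAP (448 ± 106 and 719 ± 65.8 CPM, edgeR adjusted p = 0.561), ORE1 (86.9 and 138 CPM, log2 fold 0.67 ± 0.59 SE, adjusted p = 0.454) and NYE1 (161 ± 14.4 and 150 ± 18.6 CPM, adjusted p = 0.736) did not pass. The means of RD29A, RAB18, NAP and ORE1 were higher with both, and that of NYE1 was lower. Each gene's spread was estimated over all 12 libraries, so scatter in mock and diacetyl also entered these p-values. They do not show that the levels were equal.

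In ABA-treated leaves diacetyl lowered jasmonate genes in 5 of 25 cases and raised 1, also adjusted over the list alone: the synthesis genes LOX2 and OPR3 fell 3.88-fold and 2.88-fold, and VSP1 fell to a level 82.9 times lower (95% exact interval 28.1 to 404), while JAR1, which makes the active hormone conjugate, rose 2.16-fold. The thionin THI2.1 was at 0 counts with both and at least 43.4-fold lower than with ABA, against a floor of 3 counts over the group. Its log2 fold was -8.86, and -8.00 without ABA replicate 1. BGLU18, which releases ABA from its glucose ester, fell from 3022 to 249 ± 118 CPM, 12.1-fold. PRR9, a clock gene, fell 24.7-fold among 2 lower and 3 higher of 20 (3 and 4 adjusted over the list alone), CSLA10 22.2-fold, the myrosinase-binding protein gene MBP2 27.6-fold, and the transcription factor ABI5 2.79-fold. The log2 fold of CSLA10 was -4.47, and -3.77 without ABA replicate 1.

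The term nucleosome assembly had 15 of 46 genes higher with diacetyl added where 4.90 were expected (Fisher's exact adjusted p = 0.0123). The histone gene HTA6 rose 7.41-fold, MCM4, a part of the replicative helicase, 8.57-fold (0.526 ± 0.309 to 4.76 ± 0.794 CPM), and RPA70D, a subunit of a DNA replication protein, 7.84-fold. Of 37 genes with the process term DNA replication, 5 were called higher and 1 lower. The log2 folds of HTA6 and RPA70D were 2.89 and 2.97, and 2.17 and 2.23 without ABA with diacetyl replicate 3 (edgeR adjusted p = 0.105 and 0.101). That of MCM4 was 3.099, and 3.70 without ABA replicate 2. Of 9 receptors 3 rose, including PYL7 (1.82-fold) and PYL8 (2.19-fold). SAG20 (2.23-fold) and ORS1 (2.32-fold) were the 2 of 20 senescence genes called, both higher (1 adjusted over the list alone), and EIN2 rose 1.90-fold among 3 of 19 ethylene genes (1 adjusted over the list alone). The salicylate regulator SARD1 rose 5.50-fold and UGT75B1 2.99-fold; the chaperone BIP1 fell 1.84-fold among 2 of 12 in the unfolded protein list.

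Translation genes fell again, in 96 of 361 cases where 28.9 were expected (Fisher's exact adjusted p = 2.90e-25), and the term response to jasmonic acid had 10 of 30 genes lower where 2.40 were expected (adjusted p = 0.00434). EdgeR called 0 of 8 phosphatases (0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom), 0 of 7 chlorophyll breakdown genes (0, 0 and 0) and 0 of 35 photosynthesis genes (2 at an unadjusted p under 0.05, 1 lower by DESeq2 and 2 lower by limma-voom). The chlorophyll breakdown score was 6.50 ± 0.051 with ABA and 6.22 ± 0.059 with both (exact permutation p = 0.1, the smallest that 3 against 3 allow). SEN1 (edgeR adjusted p = 0.739), ABI1 (adjusted p = 0.977), HAI1 (adjusted p = 0.772), NCED3 (adjusted p = 0.66), RD29B (adjusted p = 0.648) and PYL5 (adjusted p = 0.998) did not pass either.

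In all, 3580 genes passed the edgeR test for adding diacetyl to ABA, 1854 higher and 1726 lower, and 1405 and 2372 with upper-quartile scaling, which shifted the median fold by -0.102 (log2) and turned the median of the ABA-responsive list from 0.04 to -0.06. With only these groups in the fit 6037 passed. The groups of 8948 genes (48.5%) did not overlap, where chance gives 10%, among them 3559 of the 3580 called genes. This held for all 21 genes named here with a call, but the naming rule asked it of those picked by fold. The count of called genes was 1591 without ABA with diacetyl replicate 2 and 1833 without its replicate 1. It was 1669, 2169 and 1707 without ABA replicates 1, 2 and 3. Of the 21 genes, 9 held in every such fit: VSP1, BGLU18, OPR3, PYL7, PYL8, SAG20, EIN2, CSLA10 and MBP2. Without ABA with diacetyl replicate 1, the edgeR adjusted p was 0.0637 for LOX2, 0.133 for BIP1 and 0.153 for SARD1, and without replicate 2 it was 0.0661 for THI2.1, 0.0644 for PRR9 and 0.132 for ABI5. Without ABA replicate 3 it was 0.0546 for MCM4, 0.116 for HTA6 and 0.117 for RPA70D, and without ABA replicate 1 it was 0.128 for ORS1, 0.056 for JAR1 and 0.133 for UGT75B1 (edgeR adjusted p); each is the library whose removal gave that gene's highest p. Limma-voom did not call VSP1 (adjusted p = 0.0928), HTA6 (0.19), RPA70D (0.135) and SARD1 (0.0523). By camera 0 of 27 lists passed (3 at an unadjusted p under 0.05, 0 with an estimated correlation, 0 by fry, 2 with the replicate number as a block).

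ABA in the presence of diacetyl again raised the ABA response genes. Of 32 ABA-responsive genes 27 rose against diacetyl alone (31 adjusted over the list alone), with RD29A 5.72-fold, RD29B 34.6-fold and RAB18 16.7-fold higher. EM6 was at 0 counts with diacetyl and at least 113-fold higher with both, against a floor of 3 counts over the group. All 8 phosphatases rose, HAI1 from 3.33 ± 2.65 to 436 ± 34.7 CPM, HAI2 19.4-fold and ABI1 6.74-fold. MAPKKK18, an ABA-induced kinase, rose 101-fold, TSPO 102-fold, ABF3 24.3-fold and AFP1 29.0-fold. The log2 fold of RD29B was 5.11, and 3.65 without ABA with diacetyl replicate 1. That of HAI1 was 7.10, and 7.79 without diacetyl replicate 2, and that of ABF3 4.60, and 5.45 without diacetyl replicate 1.

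Senescence genes rose in 4 of 20 cases (6 adjusted over the list alone), including NAP (17.1-fold) and ORE1 (4.87-fold), and NYE1 rose 4.02-fold as the 1 of 7 chlorophyll breakdown genes called (2 adjusted over the list alone). PYL5 fell 3.98-fold among 5 receptors lower and 2 higher of 9, MYB60 3.46-fold and BGLU18 10.1-fold. CYP81D11 was lower, with a log2 fold of -5.08 (-2.95 without diacetyl replicate 2, -5.68 without replicate 3), and limma-voom did not call it (adjusted p = 0.0956). LTP1 rose 2.79-fold, and epidermis markers had 4 of 5 higher and 1 lower. NCED3 (edgeR adjusted p = 0.417) and SEN1 (adjusted p = 0.6) did not pass. The term response to water deprivation had 22 of 69 genes higher where 6.62 were expected (Fisher's exact adjusted p = 5.60e-05).

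In all, 3038 genes passed the edgeR test, 1702 higher and 1336 lower, and 1797 did with only these groups in the fit. The groups of 6075 genes (32.9%) did not overlap, where chance gives 10%, among them 2979 of the 3038 called genes. This held for all 20 genes named here with a call, but the naming rule asked it of those picked by fold. The count of called genes was 1659, 1977 and 1881 without ABA with diacetyl replicates 1, 2 and 3. ORE1 lost its call without diacetyl replicate 3 (edgeR adjusted p = 0.09) and MYB60 without ABA with diacetyl replicate 1 (adjusted p = 0.056). By camera 7 lists passed, of which the ABA-responsive list kept its call (adjusted p = 0.0485 with an estimated correlation) and the phosphatases did not (adjusted p = 0.0668 with an estimated correlation). The others were ABA synthesis and catabolism (5 higher, 1 lower of 11) and chlorophyll breakdown, both with an adjusted p = 0.444 with an estimated correlation, senescence (adjusted p = 0.846 with an estimated correlation), detoxification (4 higher, 2 lower of 32; adjusted p = 0.89 with an estimated correlation) and epidermis (adjusted p = 0.658 with an estimated correlation).

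Against mock, leaves given both treatments had ABA response genes higher and translation genes lower. Of 32 ABA-responsive genes 31 rose (32 adjusted over the list alone), among them RD29A 4.83-fold, RD29B 119-fold and RAB18 17.0-fold, and all 8 phosphatases rose, with HAI1 454-fold and ABI1 10.1-fold higher. NCED3 rose 8.34-fold, NAP 17.1-fold, ORE1 7.78-fold, NYE1 4.11-fold and SAG20 4.06-fold, and SEN1 did not pass (edgeR adjusted p = 0.0944). Receptors had 7 lower and 2 higher of 9, with PYR1 7.55-fold and PYL5 9.86-fold lower. Of 361 translation genes 252 fell where 71.6 were expected (Fisher's exact adjusted p = 9.07e-97), and of 99 ribosome biogenesis genes 81 fell where 19.6 were expected (adjusted p = 1.78e-38). With ABA alone 92 and 31 of these genes were called lower than mock, and with diacetyl alone 208 and 60. Without ABA with diacetyl replicate 1 the log2 fold of RD29B was 5.45 (6.89 with all libraries). Without mock replicate 3 that of HAI1 was 10.20 (8.83), that of NAP 5.72 (4.09) and that of ORE1 3.81 (2.96).

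The lipid transfer protein gene LTP3 rose 279-fold, UGT75B1 26.9-fold, LTP1 5.42-fold and LHCA4 7.70-fold. The auxin synthesis gene YUC5 was 39.4 times lower (95% exact interval 13.3 to 193) and GASA6 279 times lower (95.4 to 1360). The log2 fold of GASA6 was -7.98, -5.77 without mock replicate 1, -7.13 without ABA with diacetyl replicate 1 and -9.33 without its replicate 3, and limma-voom did not call it (adjusted p = 0.167). That of LTP3 was 8.12, and 8.71 without mock replicate 2. In all, 7834 genes passed the edgeR test, 3996 higher and 3838 lower, and 3262 and 4773 with upper-quartile scaling, which shifted the median fold by -0.152 (log2). The groups of 10323 genes (55.9%) did not overlap, where chance gives 10%, among them 7613 of the 7834 called genes. This held for all 18 genes named here with a call, but the naming rule asked it of those picked by fold. By camera 9 lists passed, and with an estimated correlation 0 did (3 at an unadjusted p under 0.05), while fry passed 12. For the ABA-responsive list the adjusted p = 0.174 with an estimated correlation, and for the phosphatases the adjusted p = 0.208 with an estimated correlation.

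The interaction asks where the effect of ABA differed with diacetyl present. Among the lowest values were AOP2 (log2 interaction -9.17 ± 1.25 SE), CYP79F1 (-8.94 ± 1.29) and BCAT4 (-7.53 ± 0.99), which are assigned to the synthesis of aliphatic glucosinolates. CYP79F1 was at 16.4 ± 10.7 CPM in mock, 442 ± 380 with diacetyl, 449 ± 157 with ABA and 24.0 ± 14.6 with both. Of 260 genes with a negative interaction, 192 were called higher in both ABA against mock and diacetyl against mock, but a negative value from the same libraries already favours genes high with each treatment alone and low in mock, so this count is no separate test. The clock genes PRR9 (-9.65), PRR7 (-5.99) and LNK2 (-2.88; chosen after its values were seen) were also negative, and 3 of 20 clock genes were called lower by edgeR (3 higher and 8 lower adjusted over the list alone) and 0 by limma-voom (8 at an unadjusted p under 0.05). Without diacetyl replicate 2 the interaction was -8.54 for AOP2, -8.21 for CYP79F1, -6.62 for BCAT4, -7.68 for PRR9 and -4.13 for PRR7. Without diacetyl replicate 3 it was -9.77 for AOP2, -9.52 for CYP79F1, -10.32 for PRR9 and -6.59 for PRR7. For CYP79F1 it was -9.55 without mock replicate 3 and -9.66 without ABA with diacetyl replicate 2.

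In the ABA pathway BGLU18 (-4.64 ± 0.58), NCED3 (-2.90 ± 0.41), PP2CA (-1.93) and AFP1 (-1.86) had a negative interaction, and PYL7 (1.06) a positive one. NCED3 was at 2.64 ± 0.382 CPM in mock, 17.35 ± 6.47 with diacetyl, 25.4 ± 5.37 with ABA and 22.5 ± 5.22 with both. VSP1 (-10.47), CYP81D11 (-7.81) and LHCB2.1 (-6.06) were also lower, and the replication genes MCM4 (4.86) and MCM2 (4.73), the amino acid permease AAP2 (3.65) and NPR1 (1.197) were higher. Of 37 genes with the process term DNA replication, however, edgeR called 0 for the interaction (15 at an unadjusted p under 0.05). The asparagine synthetase gene ASN1 had -9.84, but -4.88 without diacetyl replicate 2, where it was at 189 CPM against 1.39 and 2.49 CPM in the other diacetyl libraries. Without that library CYP81D11 had -5.70 and LHCB2.1 -4.93. Without diacetyl replicate 3 the values were -8.42 for CYP81D11, -10.49 for ASN1, -6.65 for LHCB2.1, 6.19 for MCM4, 5.97 for MCM2 and 4.59 for AAP2. ASN1 had -8.82 without ABA replicate 3, MCM4 5.46 without ABA replicate 2 and LHCB2.1 -6.76 without mock replicate 1. VSP1 had -11.67 and -9.83 without mock replicates 1 and 3, -9.78 without diacetyl replicate 1 and -11.09 without ABA with diacetyl replicate 2. The edgeR adjusted p of these 19 genes lay between 0.00892 (BGLU18) and 0.0487 (ASN1). RD29A, RD29B, RAB18, ABI1, HAI1, NAP, ORE1, SEN1, NYE1 and PYL5 did not pass, with an edgeR adjusted p between 0.151 (RD29A) and 0.998 (ORE1).

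**Figure D4:**
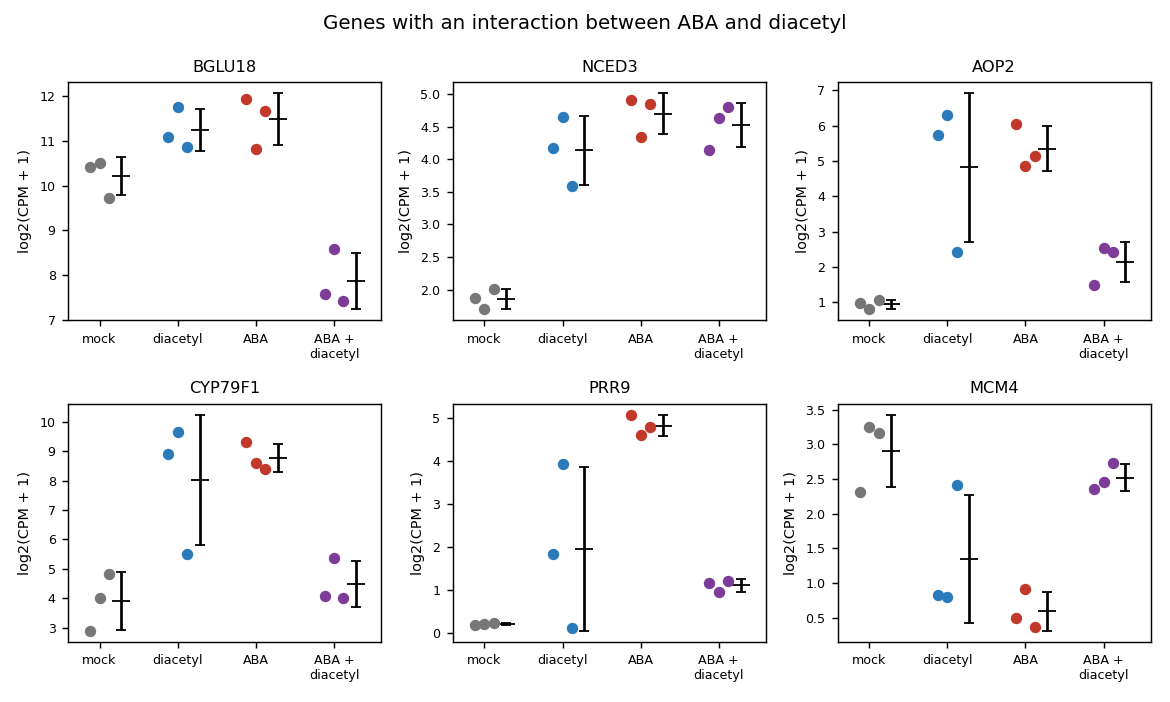
Expression of 6 genes with an interaction, as log2(CPM + 1) in each library (points) with the group mean and SD beside them (n = 3). BGLU18, NCED3, AOP2, CYP79F1 and PRR9 had a negative interaction and MCM4 a positive one; diacetyl replicate 3 lay nearer to mock than the other diacetyl libraries for AOP2, CYP79F1, PRR9 and MCM4.

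In all, 364 genes passed the edgeR interaction test, 104 higher and 260 lower, against a mean of 0.04 and a highest of 1 in 50 simulations without an interaction. These simulations drew each gene independently and so leave out shifts shared by the genes of a library. DESeq2 called 1519 and limma-voom 210. Of the 19 genes limma-voom did not call 12, and only BGLU18 kept its edgeR call without each library in turn. The count was 17 without mock replicate 2, 113 without mock replicate 3, 38, 80 and 39 without ABA replicate 1, ABA replicate 3 and ABA with diacetyl replicate 1, 105 and 83 without ABA with diacetyl replicates 2 and 3, 229 without diacetyl replicate 1 and 1539 without diacetyl replicate 3. By camera 11 lists passed, and with an estimated correlation 0 did (1 at an unadjusted p under 0.05), as with fry (6 at an unadjusted p under 0.05).

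Across the 5912 genes called in ABA against mock, the ABA fold with diacetyl had a slope of 0.434 (jackknife SE 0.166) on the ABA fold without it. Simulations without an interaction gave a mean of 0.869, between 0.854 and 0.886, and 0 of 50 were as low. Their SD was 0.00731, but they drew genes independently and so leave out shifts shared by the genes of a library. Of those genes 4926 (83.3%) had the same sign in both settings. The interaction was called against the ABA fold in 317 of them and along it in 1, where the simulations gave means of 0.04 and 0. The interaction contains the ABA fold with a minus sign, so among called genes opposition is favoured by construction. Genes higher in both settings numbered 1176, against 278 expected of independent lists, and 809 were lower in both, against 210.

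**Figure D5:**
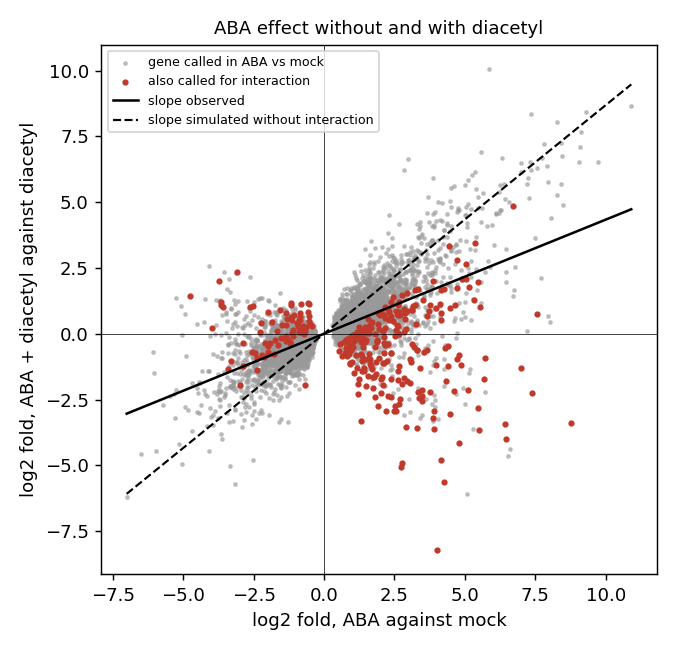
Log2 fold of ABA with diacetyl present (vertical) against that of ABA alone (horizontal) for the 5912 genes called in ABA against mock, with genes also called for interaction in red. The observed slope through 0 was 0.434 (solid line) and the simulated slope without an interaction 0.869 (dashed line).

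The diacetyl effect without ABA and that with ABA had a Pearson r of 0.209 and a Spearman rho of 0.394 across the 18452 genes, which are not independent replicates. Calls shared by both numbered 1189 higher (333 expected) and 976 lower (276 expected). The ABA fold and the diacetyl fold, both against the same 3 mock libraries, had r = 0.461 and rho = 0.426. Unchanged groups gave a simulated r of 0.488 against mock libraries that were themselves simulated from the mock means. The observed covariance was 0.502 and the simulated 0.0802, a difference of 0.422. Genes higher in both numbered 1212 (540 expected of independent lists) and genes lower in both 898 (464 expected), while unchanged groups shared 0 calls on average. Part of the excess may come from the shared mock libraries, since 3 libraries cannot be split into parts of at least 2.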

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

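The interaction test was planned; the tests on left-out libraries and on the clock genes were chosen after its result was seen. In that test the ABA effect differed with and without diacetyl for 364 genes, by edgeR at an adjusted p under 0.05. The log2 interaction was -9.17 for AOP2, -8.94 for CYP79F1, -7.53 for BCAT4, -10.47 for VSP1, -4.64 for BGLU18 and -2.90 for NCED3. It was -9.65 for PRR9, -5.99 for PRR7, -2.88 for LNK2, -7.81 for CYP81D11, -9.84 for ASN1 and -6.06 for LHCB2.1. For PP2CA it was -1.93 and for AFP1 -1.86. Values above 0 were 4.86 for MCM4, 4.73 for MCM2, 3.65 for AAP2, 1.06 for PYL7 and 1.197 for NPR1. Without diacetyl replicate 2 it was -4.88 for ASN1, -4.13 for PRR7, -7.68 for PRR9, -5.70 for CYP81D11, -4.93 for LHCB2.1, -6.62 for BCAT4, -8.54 for AOP2 and -8.21 for CYP79F1. It was 6.19 for MCM4, 5.97 for MCM2 and 4.59 for AAP2 without diacetyl replicate 3, and -9.78 to -11.67 for VSP1 without diacetyl replicate 1 and without mock replicate 1. Limma-voom did not call 12 of these 19 genes.

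Without ABA with diacetyl replicate 3, the shallow library, 83 genes were still called. Without mock replicate 2, the library whose removal took the count lowest, 17 were. The calls left did not use the library left out, but those lost may have rested on it or on the number of libraries. Simulations without an interaction gave at most 1 call, but they drew each gene independently and so set a weak bar here. The counts therefore do not decide how far the calls came from the shallow library or from any single library. Other groupings of the 12 libraries gave as many calls in 2 of 100 draws, the real one included, and the other one gave 922. In that one all 3 mock libraries counted with a plus sign and 0 of the ABA with diacetyl libraries did. The joint effect of both treatments thus entered its contrast, and whether this made its calls was not tested. Such groupings put the effects of ABA and diacetyl into the spread within groups, so this share does not by itself exclude chance. The simulations drew each gene independently, without shifts shared by the genes of a library, so they do not exclude it either. As a hypothesis, leaves may have been handled or harvested at different times of day: of 20 tested clock genes 3 passed the edgeR interaction test, a count that prompted the hypothesis and so is no independent support for it. The count also varied, since limma-voom called 0 of the 20 (8 at an unadjusted p under 0.05), DESeq2 called 3 higher and 6 lower, and the edgeR calls of PRR9 and PRR7 were lost without ABA with diacetyl replicate 1 (adjusted p = 0.068 and 0.0978) and that of LNK2 without mock replicate 2 (adjusted p = 0.114). The labels give no harvest time, and an action of diacetyl and ABA on the clock would give the same result, so the 2 cannot be told apart.

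AOP2 was at 51.9, 78.7 and 4.32 CPM in diacetyl replicates 1, 2 and 3, against 0.75 to 1.08 CPM in mock and 28.1 to 65.6 CPM with ABA. PRR9 was at 2.55 and 0.07 CPM in diacetyl replicates 1 and 3 and at 0.14 to 0.17 CPM in mock. A single count was worth 0.07 CPM in diacetyl replicate 3 and 0.0589 to 0.0778 CPM in mock. These low PRR9 levels thus rest on few counts, and the size of its interaction is uncertain. Leaving out diacetyl replicate 3 raised the interaction count to 1539. The tests on left-out libraries, which did not decide the source, replaced earlier ones that decided nothing either. Among these was the size of the interaction over the 364 genes (91.3% to 109% of the full value without any library). It decided nothing since the genes had been picked with all libraries.

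Among gene lists, 11 of 27 passed camera for the interaction, and 26 of 100 groupings of the libraries passed as many (up to 16 in another grouping). These groupings do not exclude chance for this count. Many of them kept effects of ABA or diacetyl in their contrast, so they do not show chance either. With an estimated correlation 0 passed (1 at an unadjusted p under 0.05). The camera adjusted p was 0.0185 for ABA-responsive genes (adjusted p = 0.705 with an estimated correlation), 0.00567 for phosphatases, 2.56e-05 for receptors, 0.0117 for ABA synthesis and catabolism, 0.0265 for chlorophyll breakdown, 0.00838 for reactive oxygen enzymes and 2.97e-06 for the unfolded protein response (adjusted p = 0.583 with an estimated correlation for these 6). It was 6.22e-06 for jasmonate (adjusted p = 0.656 with an estimated correlation), 0.00201 for salicylate (adjusted p = 0.705 with an estimated correlation), 0.00201 for detoxification (adjusted p = 0.728 with an estimated correlation) and 0.0237 for epidermis markers (adjusted p = 0.678 with an estimated correlation).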

How the results depend on the processing

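Leaving out both libraries that stood apart was chosen after the data had been seen; the other alternatives were planned. Against the alternatives, 140 values kept to the main result. For counts of genes and lists this meant within 1.5 times, and for the slope and correlations within their jackknife SE. Counts fell below that in 36 cases and rose above it in 6. With an absolute log2 fold of at least 1, the genes called were 3361 for ABA against mock, 2807 for diacetyl against mock, 1487 for adding diacetyl to ABA, 1640 for adding ABA to diacetyl and 4154 for both against mock. Testing against a fold of 1.2 gave 2019 for adding diacetyl to ABA, 1957 for adding ABA to diacetyl and 229 for the interaction. These thresholds call fewer genes by construction. With only the groups compared in the fit, diacetyl against mock had 3217 calls, adding diacetyl to ABA 6037 and adding ABA to diacetyl 1797. Correlations within groups were 0.939 to 0.977 for mock, 0.915 to 0.961 for diacetyl, 0.974 to 0.979 for ABA and 0.961 to 0.98 for both. The main fit shares its estimate of spread over these groups, so its counts do not rank the comparisons. The cause of the changed counts was not tested. For the interaction DESeq2 called 1519, limma-voom 210, and 71 were left without diacetyl replicate 2 and ABA with diacetyl replicate 3, a fit with fewer libraries. Lists past camera with an estimated correlation were 0 for ABA against mock, 1 for adding ABA to diacetyl, 0 for both against mock and 0 for the interaction; fry gave 2 for diacetyl against mock and 0 for the interaction. The leaf senescence score of ABA with diacetyl minus ABA was -0.025 and changed sign, to 0.007, with a pseudocount of 5. Under the alternatives for named genes, single gene list tests and list scores, 699 values stayed the same, 130 lost and 24 gained a call, and 5 scores moved.

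Same-numbered libraries did not pair: of 18 same-number pairs 3 had a correlation of deviations above 0.1 (-0.181 to 0.141), and 2 of 12 libraries matched their own number best. With the replicate number as a block, the interaction had 130 calls, and lists past camera were 8 for diacetyl against mock and 2 for adding diacetyl to ABA. The block left the 5 other gene counts within 1.5 times (5241, 5456, 2761, 2472 and 7226). With it, 2 of 24 named calls of diacetyl against mock were lost, 4 of 21 of adding diacetyl to ABA and 9 of 19 of the interaction.

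Leaving out each library gave 3815 (without ABA replicate 1) to 5934 calls for ABA against mock and 4021 (without mock replicate 2) to 6486 for diacetyl against mock. Adding diacetyl to ABA gave 1591 (without ABA with diacetyl replicate 2) to 2641, and was 1833 without replicate 1 of that group and 1669, 2169 and 1707 without ABA replicates 1, 2 and 3. Adding ABA to diacetyl gave 1659 (without ABA with diacetyl replicate 1) to 3528, and was 1977 and 1881 without replicates 2 and 3 of that group. Both against mock gave 5773 to 7666. The interaction gave 17 (without mock replicate 2) to 1539 (without diacetyl replicate 3), and was 113 without mock replicate 3, 229 without diacetyl replicate 1, 38 and 80 without ABA replicates 1 and 3, and 39, 105 and 83 without ABA with diacetyl replicates 1, 2 and 3. The slope was 0.304 (without diacetyl replicate 3) to 0.521 (without diacetyl replicate 2), the correlation of the diacetyl effects 0.102 to 0.305, and that of the ABA and diacetyl folds 0.335 to 0.522. Depth limits low genes in ABA with diacetyl replicate 3, where 3 counts are 1.3 CPM.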

Other observations

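The test of diacetyl replicate 2 alone and both mislabelling tests were chosen after their results were seen, and process terms were tested after the data had been seen; genes named only here were also chosen then. With ABA alone, besides the translation genes (92 of 361 lower), genes of DNA replication fell in 18 of 37 cases where 6.11 were expected (Fisher's exact adjusted p = 0.000371) and those of nucleosome assembly in 19 of 46 where 7.59 were expected (adjusted p = 0.00233). Of 10 genes with the term protein targeting to chloroplast 7 fell where 1.65 were expected (Fisher's exact adjusted p = 0.0062), 6 of them parts of the chloroplast import channel and its receptors, such as TOC159, TOC33 and TOC75-III. Of 230 defense response genes 70 fell where 38.0 were expected (adjusted p = 1.97e-05, Fisher's exact test). Sterol synthesis genes rose in 9 of 18 cases where 3.11 were expected (Fisher's exact adjusted p = 0.0455), including the squalene synthase genes SQS1 and SQS2.

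With diacetyl alone, 7 of 11 genes of protein targeting to mitochondria fell where 1.58 were expected (Fisher's exact adjusted p = 0.00993), including TIM10 and TOM40, and 9 of 18 pseudouridine synthesis genes fell where 2.58 were expected (adjusted p = 0.0127). Genes responding to cyclopentenones, reactive lipid products, rose in 20 of 46 cases where 8.92 were expected (Fisher's exact adjusted p = 0.0195). Leaves given both treatments had 46 of 124 genes of ubiquitin-dependent protein breakdown higher than mock where 28.5 were expected (Fisher's exact adjusted p = 0.0127), and 15 of 23 translational elongation genes lower where 4.56 were expected (adjusted p = 0.000109).

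The fall of translation genes with diacetyl was weighed against 2 technical sources. Translation genes are short (median gene length 1652 bases against 2444 for all genes), but removing the trend with length and abundance left their median log2 fold at -0.671 (SD over genes 0.507), against -0.609 before, with 334 of 361 negative, which argues against such a bias. It was not diacetyl replicate 2 alone: the lowest mock score lay 0.256 above the higher of the other diacetyl scores. ABA alone also lowered translation genes, in 92 of 361 cases, so their fall was not particular to diacetyl. An action of diacetyl on these genes is a hypothesis that these tests leave open, as is a difference in handling between dishes, which may act in the same direction and which no label records.

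Diacetyl replicate 2 stood apart from the other diacetyl libraries. With counts thinned to the same depth, its correlation with the nearer of them was 0.926 against 0.957 between those 2, a gap of 0.031, so lower depth is not the whole source. A library that had received ABA is argued against by its ABA-responsive score, 2.303 below the lowest ABA-treated library, and a mock library by its translation score, 0.668 below the lowest mock. SEN1 was at 53.8 CPM there against 2.94 and 1.69 in the others, and ASN1 at 189 against 1.39 and 2.49. No biological explanation for a single library was tested.

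Splits of 3 against 3 libraries are too few for a share under 0.05. In each of the 5 pairwise comparisons 1 of 10 groupings, the real one, gave as many genes (5912, 6261, 3580, 3038 and 7834), and edgeR called 0 in the other groupings. Those groupings mix the compared groups, which puts the treatment effect into the spread within groups. Their 0 calls therefore do not exclude chance. Of the lists, 5 of 10 groupings passed as many as the 12 of ABA against mock (up to 15 in another), 4 of 10 as many as the 7 of adding ABA to diacetyl (up to 13), and 9 of 10 as many as the 9 of both against mock (up to 15). Part of the treatment effect stayed in the contrast of each other grouping, so these list counts do not decide on chance.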
